A study of Mus musculus with 6 samples.

How the data were processed

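The series measured messenger RNA in bulk mouse liver by short-read sequencing. The mice had received an adeno-associated virus of serotype 9 (AAV9), a gene delivery vector, in which the promoter of the cardiac troponin T gene Tnnt2 drives Cre recombinase. One group of 3 libraries (replicates 10, 11 and 12) came from livers given this vector, called Cre here. The other group of 3 libraries (replicates 1, 2 and 4) came from livers given a version that also carries target sites for miR-122, a microRNA abundant in hepatocytes, called Cre-miR122 here. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the libraries came from separate animals. Sex-linked genes show that Cre replicate 10 came from a different animal than Cre replicates 11 and 12. Every pair of libraries differed by more than counting error (chi-square per degree of freedom of at least 6.19), so none was a repeat sequencing of another. The p-values measure the spread between these samples, which beyond Cre replicate 10 may be partly technical. The labels give no age, sex, dose, time after injection or sequencing batch.

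The authors deposited a table of whole-number read counts per gene, with no normalization. Per the submitters' processing notes, STAR 2.7.9a and featureCounts 2.0.1 were used with the mouse build GRCm38 (mm10). The strand setting and the treatment of reads that match several places are not given in the sources used here, so counts of overlapping, antisense and near-identical genes are uncertain. The table lists 35977 genes, of which 32501 had a matching symbol in a RefSeq gene table of the same build, and includes a row for the Cre sequence. Columns of per-sample values that match no sample of the series numbered 5, and they were not used.

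Total counts per library ran from 20340994 to 20817837. Genes were tested with the edgeR quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) with TMM scaling, the filterByExpr filter, a model with group alone and no robust dispersion. The contrast was Cre-miR122 minus Cre, two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. After the filter 14374 genes were tested. Standard errors of log2 fold changes were derived from the F statistic. CPM values were computed from the counts with TMM-scaled library sizes and are given as mean ± SD. Intervals of single counts are exact 95% Poisson intervals and cover counting error only.

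Gene lists, 42 in number, were written from general knowledge of liver biology before the data were examined, as were the samples, the tests, the rule for named genes and most alternatives. A list was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01 if at least 5 members passed the filter, which left 40 lists, and p-values were adjusted over these lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in one direction, were run beside it. Within each list the p-values of its members were also adjusted over the list alone. That was not adjusted across lists, so some lists can hold a call by chance. Sites for miR-122-5p (bases 2 to 8, 7-mer ACACTCC, 8-mer ACACTCCA) were searched in the longest annotated 3′ UTR of each gene in GENCODE mouse release M21, if at least 50 bases long. Genes with and without a site were compared with camera, and the mean difference was ranked among all 105 7-mers of the same base composition.

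The rule for named genes took called genes first. As fewer than 6 genes were called, it added the 5 genes with the smallest p in each direction with a mean of at least 1 CPM, up to 4 members with the smallest p of each list described, and a fixed set. The fixed set was Tnnt2, Aldoa, Slc7a1, Ndrg3, Gys1, P4ha1, Ccng1, Alb, Afp, Cdkn1a, Ifit1, Isg15, Xist, Ddx3y, the miR-122 gene and the Cre row. Some genes picked by the rule are not reported here. For 13 tested genes of this set, which leaves out the sex-linked genes, p-values were also adjusted over the list alone. That adjustment was not part of the planned tests and is given beside the value over all genes.

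The other settings fixed for the gene tests before the data were examined were RLE, upper-quartile and no scaling, other filters on low counts, DESeq2 1.42.0, limma-voom, robust dispersion, other thresholds, leaving out the 10 most abundant genes, protein-coding genes alone, a sex term, and leaving out each library in turn. For the list tests the settings fixed then were an estimated correlation, fry, a CPM of at least 1 in 3 libraries and leaving out each library in turn, and for the miR-122 targets also RLE scaling, no filter and the 6 best established targets alone. For the seed sites they were an estimated correlation, the 8-mer alone, the same CPM filter and leaving out each library. The other settings for lists, the sex term, the trend over GC content and length, other scalings and no filter, were added after seeing the data. Each tool was tested on simulated data made from the means and dispersions of these libraries with 200 changed genes. With edgeR, 55.2% of genes changed 1.5-fold, 89.6% of genes changed 2-fold and 98.5% of genes changed 4-fold were recovered, with 14 unchanged genes called among 14235 tested. DESeq2 called 29 unchanged genes in the same simulation. The simulation draws genes independently, so it does not carry differences between libraries that move many genes together. Its changed genes all had a mean of at least 1 CPM, and the adjustment is stricter when fewer genes change. These shares therefore do not show that larger changes are absent here, where Cre differed 3.85-fold and was not called by edgeR.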

Results

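Liver RNA was compared between mice given AAV9-Tnnt2-Cre (Cre, n = 3 libraries) and mice given the version with miR-122 target sites (Cre-miR122, n = 3 libraries), to see how the added sites affect the liver. Total counts per library lay between 20340994 and 20817837, and the common biological coefficient of variation was 11.8%. Replicate 10 of the Cre group differed from the other libraries in its sex-linked genes. It had 5 counts of Xist, the RNA of the inactive X chromosome, and 1676 counts of the Y-linked gene Ddx3y, while the other 5 libraries had 15778 to 22413 counts of Xist and at most 1 count of Ddx3y. The first 3 principal components held 30.3%, 25.3% and 19.6% of the variance, and Cre replicate 11 lay at the end of the first. That component did not separate the vectors. Cre replicate 12 lay at 7.69, with Cre-miR122 replicates 2 and 4 at 15.35 and 17.03. Cre replicates 10 and 11 lay at -10.08 and -26.43 and Cre-miR122 replicate 1 at -3.56.

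The Cre transcript was lower in livers given Cre-miR122. It stood at 2.40 ± 0.589 CPM with Cre and at 0.619 ± 0.146 CPM with Cre-miR122 (SD, n = 3 each), a 3.85-fold difference (log2 fold change -1.95, SE 0.28). Counts were 61, 50 and 37 in the Cre libraries and 12, 16 and 10 in the Cre-miR122 libraries, with no overlap. The highest Cre-miR122 library, at 0.774 CPM, had a 95% interval of 0.442 to 1.26 CPM, and the lowest Cre library, at 1.85 CPM, one of 1.30 to 2.55 CPM. Cre had the smallest p of all genes tested, yet its edgeR adjusted p was 0.816 over all 14374 genes. Adjusted over the list alone, the 13 fixed genes tested, it was 0.000817. An exact permutation test gave a two-sided p of 0.1, the smallest that 3 libraries against 3 allow. Tnnt2 itself, the gene of cardiac troponin T, was at 0.587 ± 0.105 CPM with Cre and 0.773 ± 0.663 CPM with Cre-miR122, and its log2 fold change of 0.39 turned to -0.50 without Cre-miR122 replicate 1 and to -0.015 with limma-voom.

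**Figure D1:**
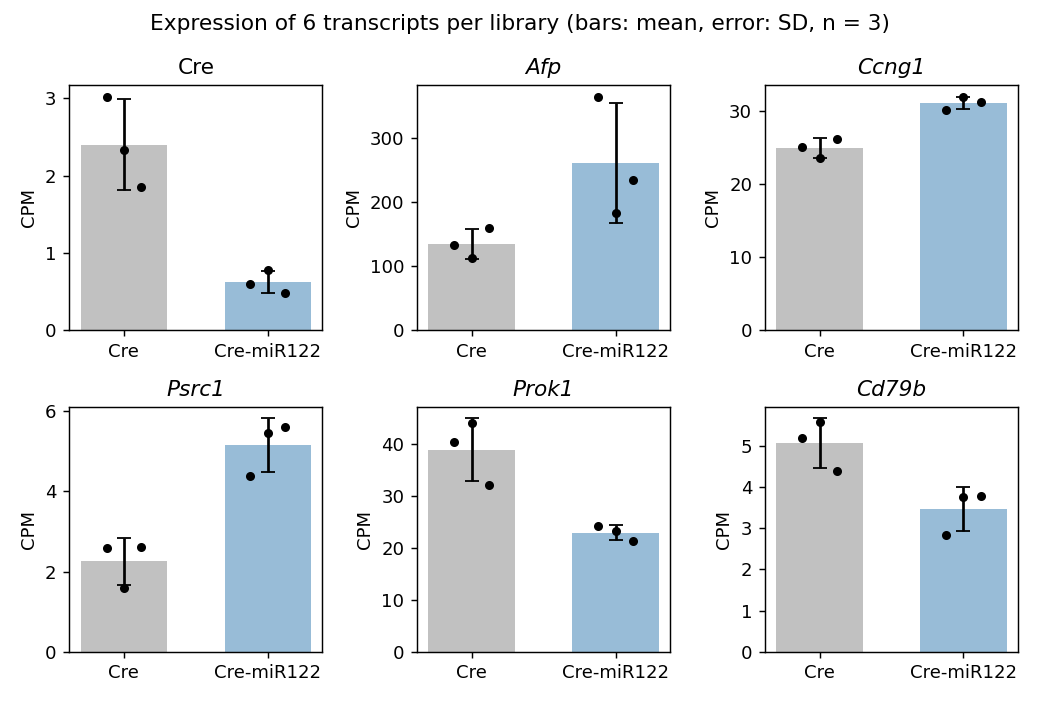
CPM of Cre, Afp, Ccng1, Psrc1, Prok1 and Cd79b in each library (points), with the group mean (bars) and SD (error bars, n = 3 per group). The Cre transcript lay between 0.484 and 0.774 CPM in the Cre-miR122 libraries and between 1.85 and 3.02 CPM in the Cre libraries.

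Across the liver transcriptome, 0 genes were called higher and 0 lower with Cre-miR122 by edgeR, the smallest adjusted p being 0.816. At an unadjusted p under 0.05 there were 397 genes higher and 381 lower, 778 in all, where 719 are expected by chance. That count was 425 without Cre-miR122 replicate 4, 467 without Cre replicate 11 and 1535 without Cre replicate 12. It was 1169 without a filter on low counts, which tests more genes, so the 719 expected does not apply to it. Grouping Cre replicates 10 and 11 and Cre-miR122 replicate 1 against the rest gave 2328, and the other mixed groupings 296 to 843. DESeq2 called 1 gene higher and 2 lower, and limma-voom called 0. The groups did not overlap for 11.1% of genes, where chance gives 10% with 3 libraries against 3. The genes with the smallest p on the higher side, none past the threshold, were Lmbrd2 (log2 fold change 1.01, SE 0.17), Psrc1 (1.20, SE 0.21), Morc4 (0.52, SE 0.098), Garem (0.54, SE 0.12) and Klf9 (0.35, SE 0.076). On the lower side, after Cre, they were Prok1 (-0.76, SE 0.12), Bach2 (-0.70, SE 0.14), Fads3 (-0.62, SE 0.13) and Mmd2 (-0.39, SE 0.083). Psrc1 encodes a spindle protein, Klf9 a transcription factor, Bach2 a transcription factor of lymphocytes, and Prok1 a secreted prokineticin. DESeq2 gave adjusted p of 0.00188 for Prok1, 0.0160 for Cre and 0.0436 for Psrc1, and without a filter on low counts edgeR called Cre and Prok1 (adjusted p = 0.0392 for each).

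Known targets of miR-122 were not called as a group. Of 51 tested members of the target list, 21 had a log2 fold change above 0 and 30 below, with a median of -0.023 (camera adjusted p = 0.672, and adjusted p = 0.820 with an estimated correlation). The camera direction turned upward without Cre replicate 10 and without Cre-miR122 replicate 2, where the medians were -0.0052 and -0.0075. No member passed the test over all genes or adjusted over the list alone. Among the best established targets, Aldoa, the muscle-type aldolase, had a log2 fold change of -0.20 (SE 0.17), the amino acid transporter Slc7a1 -0.28 (SE 0.22), and P4ha1, a subunit of the collagen prolyl hydroxylase, -0.25 (SE 0.11). Aldoa was at -0.010 without Cre replicate 10, -0.35 without Cre replicate 12, -0.35 without Cre-miR122 replicate 1 and -0.10 without Cre-miR122 replicate 2, and Slc7a1 at -0.13 without Cre-miR122 replicate 1. Ndrg3 was at 0.11 (SE 0.12) and the glycogen synthase gene Gys1 at -0.021 (SE 0.13). Without Cre replicate 10 Ndrg3 turned to -0.0033 and Gys1 to 0.039, and without Cre-miR122 replicate 2 Gys1 was at 0.025. Ccng1, which encodes cyclin G1 and is also a p53 target, went the other way, from 24.9 ± 1.36 to 31.1 ± 0.876 CPM (log2 fold change 0.32, SE 0.080). Its edgeR adjusted p was 0.816 over all genes and 0.0132 over the 13 fixed genes. Genes with a 7-mer miR-122 site in the 3′ UTR, 1162 of 12622, differed from genes without one by 0.013 on the log2 scale (camera p = 0.483, and p = 0.296 with an estimated correlation). That difference ranked 98 from the top among 105 7-mers of the same composition, whose differences ran from 0.0083 to 0.039. For genes with the longer site, 412 in number, it was 0.011, and camera did not call them either. The miR-122 gene on chromosome 18 (65248861 to 65248926) was at 0.625 ± 0.414 CPM with Cre and 0.520 ± 0.180 CPM with Cre-miR122, and its log2 fold change of -0.27 turned to 0.29 without Cre replicate 11. Such counts of mRNA libraries do not measure the mature microRNA.

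Of the 40 gene lists tested, camera with its preset correlation called 19, of which 6 were higher and 13 lower with Cre-miR122. With an estimated correlation 0 were called, the smallest adjusted p being 0.429, and fry called 0, with a smallest adjusted p of 0.342. The adjustment gave many lists the same 0.429, so that value does not rank them. Their unadjusted camera p with an estimated correlation ran from 0.0122 for B cell genes to 0.150 for gluconeogenesis genes. Among the 19 lists the estimated correlation ran from 0.078 for acute-phase genes to 0.79 for ribosomal genes, above the preset 0.01. It was 0.55 for cell cycle and 0.48 for interferon-stimulated genes. The preset p-values of such lists are therefore too small and do not stand as evidence on their own. For 6 of the 19 lists the mean deviations of the libraries did not overlap between the groups, and the lists with the smallest camera p, cell cycle and interferon-stimulated genes, were not among these 6.

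The cell cycle list was called higher with Cre-miR122 by camera with its preset correlation. Of 40 cell cycle genes 38 had a log2 fold change above 0, with a median of 0.38 (camera adjusted p = 5.61e-19, and adjusted p = 0.429 with an estimated correlation). None passed the test over all genes or adjusted over the list alone. The proliferation marker Mki67 was at 49.4 ± 11.1 CPM with Cre and 72.4 ± 5.59 CPM with Cre-miR122, and the mitotic cyclin gene Ccnb1 at 10.7 ± 3.50 and 18.4 ± 4.50 CPM. Hmmr had a log2 fold change of 0.89 (SE 0.28) and the survivin gene Birc5 one of 0.56 (SE 0.18). Cre replicate 11 was lowest, 0.54 below the mean of the 6 libraries on the log2 scale, and without it the median was 0.25. The groups overlapped, Cre replicate 10 lying at 0.061 and Cre-miR122 replicate 1 at -0.016.

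Several lists of immune genes were called lower by camera with its preset correlation, and none with an estimated correlation. The T and NK cell list was not called (median -0.18, camera adjusted p = 0.102). The B cell list, written for B cells and plasma cells together, had 24 members, of which only 14 had a row in the count table. Of 13 B cell genes tested 12 had a log2 fold change below 0, with a median of -0.64 (camera adjusted p = 1.28e-11, and adjusted p = 0.429 with an estimated correlation), and 8 were lower adjusted over the list alone. They included Fcmr, the receptor for IgM (-1.25, SE 0.27). Its counts were few, 30, 23 and 24 with Cre and 11, 11 and 10 with Cre-miR122. The B cell transcription factor Pax5 (-0.65, SE 0.20) and the B cell receptor chain Cd79b (-0.55, SE 0.17) were also among them. Of 54 interferon-stimulated genes 50 lay below 0, with a median of -0.32 (camera adjusted p = 3.69e-15, and adjusted p = 0.429 with an estimated correlation). The median was -0.14 without Cre replicate 11, which lay 0.42 above the mean of the 6 libraries. The groups overlapped for this list too, Cre replicate 10 lying at -0.13 and Cre-miR122 replicate 2 at 0.0040. Dhx58 was at -0.45 (SE 0.13), the chemokine gene Cxcl10 at -0.69 (SE 0.21), Gbp4 at -0.60 (SE 0.20) and Igtp at -0.81 (SE 0.28), and without Cre replicate 11 Gbp4 was at -0.38 and Igtp at -0.43. Ifit1, an interferon-induced gene fixed in advance, was at -0.38 (SE 0.23), with -0.14 without Cre replicate 11 and -0.58 without Cre-miR122 replicate 2, and Isg15 had too few counts to be tested, a count that is uncertain for reads that match several places. All 19 genes of the list for dendritic cells and MHC class II lay below 0, with a median of -0.26 (camera adjusted p = 2.03e-08, and adjusted p = 0.429 with an estimated correlation). Among them were H2-DMa (-0.69, SE 0.19), H2-Ab1 (-0.70, SE 0.20), Cd74 (-0.75, SE 0.22) and H2-Eb1 (-0.64, SE 0.22). Without Cre replicate 11 H2-Ab1 was at -0.41, Cd74 at -0.40 and H2-Eb1 at -0.33, and the median of the list was -0.19. With all 6 libraries the median was -0.44 when a CPM of at least 1 in 3 libraries was required. Neutrophil and monocyte genes had a median of -0.32 over 20 genes (camera adjusted p = 2.75e-05, and adjusted p = 0.429 with an estimated correlation), with the calprotectin genes S100a8 at -0.52 (SE 0.18) and S100a9 at -0.45 (SE 0.16). The median of that list was -0.20 without Cre replicate 11. Smaller differences stood in the lists of DNA sensors (median -0.17, camera adjusted p = 0.000218), MHC class I (-0.13, adjusted p = 0.000857), Kupffer cells (-0.19, adjusted p = 0.00252) and inflammatory cytokines (-0.16, adjusted p = 0.0131). The adjusted p of these lists lay between 0.429 and 0.617 with an estimated correlation. Without Cre replicate 11 camera no longer called the lists of MHC class I (median -0.028), Kupffer cells (-0.067) and cytokines (-0.068). Without Cre replicate 10 the median for MHC class I was -0.23, and with the trend over GC content and length removed it was -0.077. The Kupffer cell call was also lost without Cre-miR122 replicate 1 (median -0.074), and the cytokine call without Cre replicate 12 (-0.082) or Cre-miR122 replicate 4 (-0.11).

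**Figure D2:**
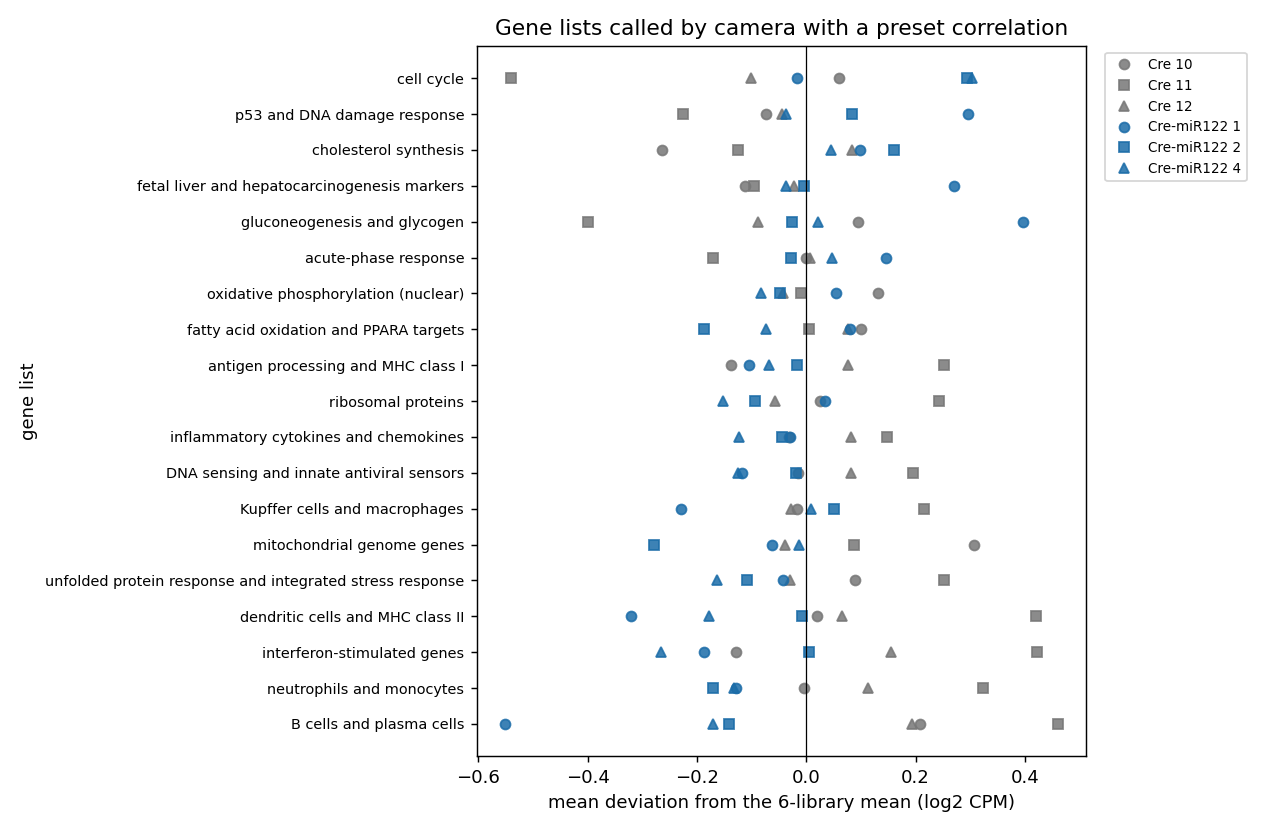
Mean deviation of each library from the mean of the 6 libraries (log2 CPM, horizontal axis) for the 19 gene lists called by camera with a preset correlation (vertical axis), Cre libraries in grey and Cre-miR122 libraries in blue. For cell cycle genes Cre replicate 11 lay at -0.54, and for B cell genes Cre-miR122 replicate 1 lay at -0.55.

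Lists of fetal liver and metabolic genes were also called by camera with its preset correlation, and none with an estimated correlation, where the smallest adjusted p was 0.429. Afp, the fetal serum protein gene, was at 135 ± 23.5 CPM with Cre and 261 ± 94.3 CPM with Cre-miR122 (log2 fold change 0.95, SE 0.23, and 0.63 without Cre-miR122 replicate 1). Its edgeR adjusted p was 0.816 over all genes and 0.0132 over the 13 fixed genes, while Alb, the albumin gene, was at 0.073 (SE 0.14) and turned to -0.015 without Cre replicate 11. The fetal list had 16 of 24 genes above 0 and a median of 0.17 (camera adjusted p = 0.00171, and adjusted p = 0.429 with an estimated correlation). H19, an imprinted non-coding RNA, was at 0.43 (SE 0.12), Gpc3 at 0.33 (SE 0.11) and Golm1 at 0.28 (SE 0.12). H19 was abundant in both groups, at 6918 ± 861 CPM with Cre and 9312 ± 246 CPM with Cre-miR122. Gpc3 was at 90.2 ± 8.56 and 113 ± 14.6 CPM. The labels give no age, so whether these were adult livers is not known. Without Cre-miR122 replicate 1 the fetal list was no longer called, with a median of 0.042, and without Cre replicate 10 its median was 0.099. Cholesterol synthesis genes had a median of 0.17, with 22 of 25 above 0 (camera adjusted p = 3.32e-07, and adjusted p = 0.429 with an estimated correlation). Idi1 was at 0.77 (SE 0.22), Msmo1 at 0.40 (SE 0.13) and Srebf2, the regulator of the pathway, at 0.28 (SE 0.10). The male library, Cre replicate 10, was lowest for this list, 0.26 below the mean. The median was 0.081 without it and 0.31 without Cre replicate 12.

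The p53 list had 25 of 34 genes above 0 and a median of 0.23 (camera adjusted p = 3.29e-06, and adjusted p = 0.429 with an estimated correlation), and 1 gene, Psrc1, was higher adjusted over the list alone. The median was 0.14 without Cre-miR122 replicate 1. Eda2r was at 1.05 (SE 0.34), from few counts, 11, 11 and 19 with Cre and 33, 33 and 19 with Cre-miR122. Phlda3 was at 0.58 (SE 0.20, and 0.36 without Cre-miR122 replicate 1). Cdkn1a, the p21 gene, was at 0.19 (SE 0.35) but turned to -0.38 without Cre-miR122 replicate 1. Genes of the unfolded protein response had a median of -0.23 (camera adjusted p = 7.77e-06, and adjusted p = 0.429 with an estimated correlation), with Hyou1 at -0.39 (SE 0.11), Manf at -0.50 (SE 0.14) and the chaperone gene Hspa5 at -0.36 (SE 0.11), while the sensor gene Ern1 was at 0.42 (SE 0.13). The median was -0.14 without Cre replicate 11. All 59 ribosomal protein genes lay below 0, with a median of -0.16 (camera adjusted p = 7.53e-10, and adjusted p = 0.593 with an estimated correlation), and so did all 13 genes of the mitochondrial genome, with a median of -0.22 (camera adjusted p = 3.53e-05, and adjusted p = 0.429 with an estimated correlation). Of the mitochondrial genes ATP6 (61.3 CPM with Cre), COX2 (37.7 CPM) and COX3 (43.8 CPM) were far below ND4 (5274 CPM) and ND2 (7694 CPM), and their counts are uncertain because the treatment of reads that match several places is not given in the sources used here. The median of the ribosomal list was -0.062 without Cre replicate 11 and -0.057 with the trend over GC content and length removed, and that of the mitochondrial list -0.10 without Cre replicate 10. The male library had the highest share of mitochondrial counts, 8.08%, against 5.93% to 6.67% in the other libraries.

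Gluconeogenesis genes had a median of 0.17, with G6pc at 0.65 (SE 0.21) and Ppp1r3c at 0.25 (SE 0.082), and acute-phase genes one of 0.071 (camera adjusted p = 0.000218 and 0.00875, and adjusted p = 0.429 for each with an estimated correlation). Camera no longer called either list without Cre-miR122 replicate 1, where the medians were 0.077 and 0.11, nor the acute-phase list without Cre replicate 11 (0.071). The acute-phase median was 0.14 without Cre replicate 12 and 0.13 without Cre-miR122 replicate 2, and the gluconeogenesis median 0.11 without Cre replicate 11. Fatty acid oxidation genes had a median of -0.087, with the fatty acid binding protein gene Fabp1 at -0.43 (SE 0.12), and nuclear genes of oxidative phosphorylation one of -0.063 (camera adjusted p = 0.0131 and 0.0432, and adjusted p = 0.593 and 0.809 with an estimated correlation). The call for fatty acid oxidation was lost without Cre replicate 10 (median -0.062), Cre replicate 12 (-0.047) or Cre-miR122 replicate 2 (-0.018). The call for oxidative phosphorylation was lost without Cre replicate 10 (median -0.0089, camera pointing upward), Cre-miR122 replicate 2 (-0.058) or Cre-miR122 replicate 4 (-0.027). Its median was -0.11 without Cre replicate 12 and -0.13 without Cre-miR122 replicate 1. With all 6 libraries this call was also lost with the trend over GC content and length removed, where the median turned to 0.013. It was lost without a filter on low counts (-0.058) too. A sex term lost both calls (-0.062 and -0.0089), but it fits Cre replicate 10 alone and so repeats the run without that library.

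With its preset correlation and the model with group alone, camera called none of the other 21 lists tested when all 6 libraries and the filterByExpr filter were used. These covered miR-122 targets and the microRNA pathway, periportal and pericentral genes, drug, bile acid and fatty acid metabolism, secreted proteins, hepatocyte transcription factors, sex-biased genes, the clock, matrix, oxidative stress and heat shock, and markers of T and NK, stellate, endothelial, biliary, erythroid and non-liver cells. Within them Igfals, which encodes a carrier protein of insulin-like growth factors (log2 fold change -0.36, SE 0.081), and the erythropoietin receptor gene Epor (-0.69, SE 0.17) were lower adjusted over the list alone (edgeR adjusted p = 0.0444 and 0.0454), and edgeR gave an adjusted p of 0.816 for both over all genes. With no adjustment across the lists, such calls close to the threshold can arise by chance.

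Several of these lists were called by camera with its preset correlation when 1 library was left out, with a sex term or with another filter, and no estimated correlation was run in those settings. Without the male library, Cre replicate 10, the periportal (median 0.26) and matrix (0.11) lists were called higher and the pericentral (-0.081), T and NK cell (-0.26) and erythroid (-0.23) lists lower. A sex term also called these 5 lists, in the same directions. Only Cre replicate 10 had male sex-linked expression, so that term acts like leaving this library out and is no separate check. Without Cre replicate 11 the pericentral list was called higher (0.13) and the matrix (-0.18), stellate (-0.16) and endothelial (-0.13) lists lower, so the pericentral and matrix lists took opposite directions in these runs. Without Cre replicate 12 the drug metabolism (0.16) and pericentral (0.13) lists were called higher. Female-biased genes were called lower without Cre-miR122 replicate 1 (-0.092), clock genes higher without Cre-miR122 replicate 2 (0.088) and immediate early and heat shock genes higher without Cre-miR122 replicate 4 (0.034). The T and NK cell list was also called lower (-0.20) when a CPM of at least 1 in 3 libraries was required.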

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

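The sex term, GC, scaling and no-filter alternatives for lists and the sex term for the miR-122 tests were chosen after seeing the data. The settings applied to the Cre transcript were those fixed beforehand for the gene tests, but following this transcript through them was chosen afterwards. No paired analysis was possible because the groups share no replicate numbers. The sex term fits the only male library, Cre replicate 10, so its results almost repeat the run without that library and are no separate check. The count of 0 genes called higher and 0 lower became 2 lower without a filter on low counts, and 1 higher and 2 lower with DESeq2; it stayed at 0 in the other alternatives, including each run without 1 library. The genes at unadjusted p under 0.05, 778 in all, numbered 425 to 1535 without 1 library and 1169 without a filter. The Cre transcript passed the threshold over all genes without a filter (log2 fold change -1.94, edgeR adjusted p = 0.0392) and with DESeq2 (-1.95, adjusted p = 0.0160), and ran from -2.14 to -1.75 without 1 library; it has no row when protein-coding genes alone are kept. Lists called fell from 19 to 0 with an estimated correlation and to 0 with fry. Without a filter camera no longer called the cytokine (adjusted p = 0.0608) and nuclear oxidative phosphorylation (0.0564) lists. The miR-122 targets stayed uncalled, with medians of -0.029 to -0.0052 without 1 library and -0.0052 with the sex term; the camera direction turned upward with the sex term, without Cre replicate 10 and without Cre-miR122 replicate 2. The difference of seed site genes (0.0042 to 0.020 without 1 library) stayed above 0 and uncalled. With the sex term Ndrg3 turned to -0.0034, Gys1 to 0.039, the fatty acid oxidation call was lost (median -0.062) and the median of nuclear oxidative phosphorylation was -0.0089 with camera pointing upward; with the GC and length trend removed that median was 0.013 (the mitochondrial list had no GC values, so that check was void for it), and with limma-voom Tnnt2 was at -0.015. Without 1 library Ndrg3 ran from -0.0033 to 0.18, Gys1 from -0.066 to 0.039, Alb from -0.015 to 0.14, Mir122 from -0.69 to 0.29, Tnnt2 from -0.50 to 0.85, Cdkn1a from -0.38 to 0.48 and oxidative phosphorylation from -0.13 to -0.0089. The cause was not tested, except that leaving out a library removes a sample. No scaling moved the median of all genes by over 0.1. Depth limits the Cre transcript, which had 10 to 61 counts per library, and also Fcmr (10 to 30) and Eda2r (11 to 33).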

Other observations

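The tests of single libraries, blood and other liver cells in this part were chosen after the results were seen. The GC and length test and the imprinted gene test were also chosen after seeing the data, but what each outcome would mean was written down before the result of that test was seen, as it was for the other splits and the seed site test. The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 0 genes and the highest other split 7; with a real count of 0 all 10 splits call at least as many by construction, so this comparison says nothing about chance. The real split called 19 lists and the highest other split 24, and 4 of the 10 splits called at least 19. The size of the list median in the real split and in the highest other was 0.64 and 0.44 for B cell genes, 0.38 and 0.44 for cell cycle genes, 0.32 and 0.36 for interferon-stimulated genes, 0.26 and 0.33 for dendritic cell and MHC class II genes, and 0.174 and 0.205 for cholesterol synthesis genes.

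The cell cycle list was called higher with Cre-miR122 by camera with its preset correlation, but not with an estimated one (adjusted p = 0.429). The male library was argued against as the source, since without Cre replicate 10 the median log2 fold change of the list was 0.52, with a standard error between libraries of 0.21. A trend with GC content or transcript length was argued against as the whole cause only in that its removal left the median at 0.37, against 0.38 before. The standard error between libraries was 0.21, taken from values before the removal, so the size of what remained is uncertain. Cre replicate 11 alone stays possible: without it the median was 0.25 with a standard error between libraries of 0.15, too wide to tell. A difference between the vectors stays open as well, and the split of Cre replicate 10 with Cre-miR122 replicates 2 and 4 against the rest moved the list median by 0.44, against 0.38 in the real split. Age, which the labels do not give, was not tested for this list.

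The B cell list was called lower with Cre-miR122 by camera with its preset correlation, but not with an estimated one (adjusted p = 0.429) or by fry (adjusted p = 0.342). More blood in the Cre livers as the whole cause was argued against only weakly by the haemoglobin genes, near-identical copies that can share reads. Their median log2 fold change was 0.12 (SE 0.22 to 0.35 per gene, with Hbb-bs from 99.9 to 288 CPM). Without Cre replicate 10 it was -0.17, where the B cell median was -0.59. In that run Hbb-bt (-0.26, SE 0.18) lay above the B cell upper quartile (-0.45) by little more than its standard error, too little to exclude blood. A lower share of all cells other than hepatocytes was argued against by the endothelial, stellate and biliary lists. Their lowest median was -0.048, against an upper quartile of -0.45 for B cell genes. Without Cre replicate 11 the medians were -0.16 for the stellate, -0.13 for the endothelial and 0.010 for the biliary list. The B cell median was -0.47 without Cre replicate 11, with a standard error between libraries of 0.17. This argued against that library alone setting the difference, but the spread is wide. Without Cre-miR122 replicate 1, the library furthest from the mean, the B cell median was -0.44, the smallest of the runs without 1 library. Camera with its preset correlation still called the list there (adjusted p = 4.78e-06). A lower number of B cells in the Cre-miR122 livers stays a hypothesis, and age, dose and the region of liver sampled were not tested.

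Afp and H19 had higher means with Cre-miR122, but neither passed the edgeR test over all genes (adjusted p = 0.816 for each), so any explanation concerns a difference that chance may have given. Were miR-122 held by the vector sites, its targets would rise, yet genes with a miR-122 seed site shifted by 0.013 (interval over genes 0.0003 to 0.025, genes not being independent replicates), which argues against a general release of targets above 0.05 but not against one limited to a few targets. A younger stage of the Cre-miR122 livers could not be decided: 14 tested imprinted and fetal growth genes, listed from memory, had a median of 0.062 (camera p = 0.183, and p = 0.425 with an estimated correlation). Cre-miR122 replicate 1 had the highest Afp, 366 CPM, and without it the log2 fold change of Afp was 0.63 (SE 0.16) in place of 0.95 and that of H19 0.41 (SE 0.15). A biological difference between the vectors stays open as a hypothesis.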
